A study of Homo sapiens with 6 samples.

How the data were processed

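RNA was sequenced from 6 samples of Huh-7, a human hepatocellular carcinoma line, in 2 groups of 3 libraries: cells given a plasmid that expresses ALKBH5 (oeALKBH5) and control cells. ALKBH5 is a demethylase that removes N6-methyladenosine (m6A) from RNA. Per the labels' protocols, the plasmid was electroporated with 3 pulses of 1250 V and 20 ms, RNA was taken 60 h later, and libraries were made with an mRNA kit. The same treatment text stands beside the control samples, while the series design calls them parental cells, so the labels do not state whether the controls were electroporated or received an empty plasmid. The libraries carry numbers as biological replicates. No label says that they came from separate cultures or transfections, so p-values measure the spread between these samples, which may be technical.

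The authors deposited estimated counts per RefSeq transcript and, for the same transcripts, FPKM values (fragments scaled by transcript length and library depth). Per the submitters' processing notes, HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8 and the build GRCh38.p13 were used; the role of each tool, the filters and the strand setting are not given in the sources used here. The deposited estimated counts covered 80668 protein-coding transcripts of 18030 genes and were not scaled between libraries. Estimated counts divide reads among similar transcripts by a model, so members of near-identical families and overlapping genes are uncertain one by one.

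Transcript values were summed to genes by Entrez identifier, and the sums of estimated counts were rounded to whole numbers. Gene symbols were matched for 17881 genes; the other 149 held 0.0264% of the counts. The tables held no gene of the mitochondrial chromosome and no noncoding transcript. Summed totals ran from 18607084 to 18826479 in oeALKBH5 and from 19265686 to 19378030 in control libraries. No pair of libraries agreed within counting noise, so all 6 were kept as separate replicates.

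The main test was edgeR 4.0.16 (R 4.3.3), with TMM scaling, its expression filter at a minimum count of 10, the robust quasi-likelihood fit with group as the single term, a two-sided test and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05, and passing genes with an absolute log2 fold change of at least 1 were also counted. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic. Levels in CPM used TMM-scaled library sizes. As a second readout, the authors' FPKM values were tested on log2(FPKM + 1) with limma 3.58.1, for genes with an FPKM of at least 1 in 3 libraries. A fold change on that scale understates the change of low genes.

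The test, the alternatives, 40 gene lists and the rule for named genes were set before the data were examined. The rule took ALKBH5, then the 10 largest rises and 10 largest falls among passing genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, then up to 2 members that rose and 2 that fell in each list, by p. Lists of quality genes or other cell types were named by their most abundant members. Members outside the rule were named after their values were seen, mostly where 5 or fewer of a list moved one way. The 37 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it; fry asks whether a list's genes move, on balance, one way, and compares the list with no other genes. The lists of mitochondrially encoded mRNAs and nuclear noncoding RNAs had 0 measured members and were not analysed here.

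Alternatives were DESeq2 size factors, upper quartile scaling, library size alone, no filter, filters at a CPM of 1 and at a mean count of 50, DESeq2 1.42.0, limma-voom, the replicate number as a block, ALKBH5 left out, an adjusted p under 0.01, and leaving out each library in turn. Transcript length, GC content and exon lengths came from GENCODE release 29 on GRCh38, with a length for 98.6% of tested genes. Isoform-level values were not analysed here. Figures were drawn with matplotlib 3.10.9.

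The scripts were tested on simulated data: counts for 14036 genes drawn for 3 against 3 libraries, with 50 genes changed at each of 4 fold sizes. edgeR recovered 52% of genes changed 1.25-fold, 82% at 1.5-fold, 86% at 2-fold and 98% at 4-fold, with 6 false calls. DESeq2 recovered 46%, 78%, 86% and 96% at those sizes with 3 false calls, and limma-voom 52%, 82%, 86% and 98% with 6. On the simulated log2(value + 1) scale limma recovered 86% of 2-fold changes among 13318 genes, with 5 false calls. Of 10 simulated lists, camera called the 1 shifted list (20 genes, 1.3-fold) and 0 of the others. The simulated genes were drawn independently of each other, and only a small share was changed. The simulation therefore does not show how the tests perform on correlated genes or where many genes change.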

Results

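Messenger RNA from Huh-7 cells was profiled to ask how ALKBH5 overexpression changes gene expression, with 3 oeALKBH5 and 3 control libraries. The libraries held 18708513, 18607084 and 18826479 estimated counts in oeALKBH5 and 19265686, 19348109 and 19378030 in control. Between 16601 and 16855 genes had a count above 0. The 10 most abundant genes took 5.2% to 5.3% of counts in oeALKBH5 and 6.06% to 6.17% in control libraries.

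ALKBH5 mRNA was 1.87-fold higher in oeALKBH5 cells. The gene (Entrez 54890) lies on chromosome 17 at 18183078 to 18209954 on the plus strand of GRCh38 (GENCODE release 29), and its principal transcript has 4 exons over 2748 nt. Its level was 137 ± 29.5 CPM in oeALKBH5 and 73.4 ± 2.56 CPM in control (SD, n = 3 each), a log2 fold change of 0.90 (SE 0.177, edgeR adjusted p = 0.0154). The oeALKBH5 libraries held 169, 133 and 110 CPM, all above the highest control at 75.5 CPM. In the authors' FPKM values the level was 45.4 ± 9.89 against 23.0 ± 0.917 (limma adjusted p = 0.00162). The call was lost without control replicate 2 (adjusted p = 0.0529) and without control replicate 3 (adjusted p = 0.0589), with values from 3.38e-10 to 0.0589 over all alternatives. It was also lost with the replicate number as a block (adjusted p = 0.0538).

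The change reached far beyond ALKBH5. Of 14168 genes tested, 2948 were higher and 3114 lower in oeALKBH5 cells (edgeR). Most changes were small: the median absolute log2 fold change of passing genes was 0.30, and 303 genes passed with at least 1, 174 higher and 129 lower. That count depended on the settings: it was 147 with a mean count of at least 50. It was 73 on the log2(FPKM + 1) scale, where the test and the filter also differed. The biological coefficient of variation was 4.61%. The first principal component of log2 CPM held 56.0% of the variance, with oeALKBH5 libraries between -25.65 and -17.5 and controls between 20.95 and 21.95. On the second component, with 12.8%, oeALKBH5 replicate 1 stood apart from replicates 2 and 3 (18.21 against -6.29 and -15.03). The oeALKBH5 libraries differed more from each other (chi-square per degree of freedom 3.28 to 8.05) than the controls did (1.67 to 2.45). The split by direction depended on scaling. With library size alone, 4266 genes were higher and 2047 lower, and the median of all genes moved to 0.085. On FPKM, where the test and the filter differed as well as the scaling, 3535 were higher and 1977 lower.

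Metallothionein genes led the rise. These encode small cysteine-rich proteins that bind zinc and copper. MT1X was 20.6-fold higher (log2 fold change 4.37, SE 0.239, adjusted p = 5.62e-05), from 3.26 ± 0.363 to 67.4 ± 14.2 CPM. MT1E was 6.65-fold higher (2.73, SE 0.058, adjusted p = 7.32e-18) and MT1F 3.85-fold (1.95, SE 0.0631, adjusted p = 8.37e-15). Because these genes are near-identical, their sum was also taken, after their values were seen: it was 1002 ± 67.9 CPM in oeALKBH5 and 280.0 ± 5.60 CPM in control, 3.58-fold higher. IGFBP1, a secreted insulin-like growth factor binding protein of liver, rose 4.21-fold and the cytokine LIF 3.59-fold. CNN1, the smooth muscle calponin that binds actin, rose 4.34-fold. The less abundant LGI4 and PPFIA4 rose 5.46-fold and 5.21-fold. PNCK, a calmodulin kinase, rose 4.73-fold with wide error (log2 fold change 2.24, SE 0.614). Its log2 fold change was 1.59 without oeALKBH5 replicate 1, which held 6.71 CPM against 2.80 and 2.14 in the others. Its call was lost without control replicates 1, 2 and 3 in turn (adjusted p = 0.063, 0.116 and 0.142) with limma-voom (adjusted p = 0.0566) and without the filter (adjusted p = 0.0701), against 2.29e-06 to 0.142 over all alternatives. FSBP, whose gene overlaps RAD54B, rose 3.29-fold; without oeALKBH5 replicate 1 its adjusted p was 0.0526, in a range of 1.16e-06 to 0.0526.

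**Figure D1:**
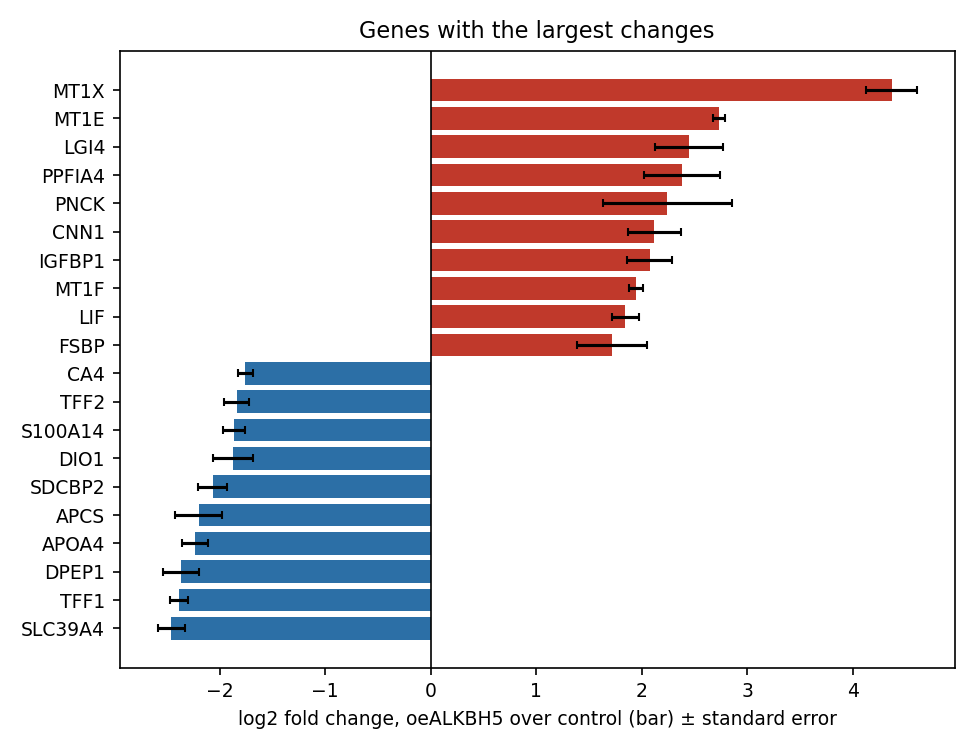
Log2 fold change (oeALKBH5 over control, 3 libraries each) of the 10 genes with the largest rise and the 10 with the largest fall; bars are edgeR estimates and whiskers standard errors. MT1X reached 4.37 and SLC39A4 -2.46.

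Among passing genes with a mean log2 CPM of at least 1 and no overlap between groups, the largest fall was that of SLC39A4, which encodes the zinc importer ZIP4. It was 5.49-fold lower (log2 fold change -2.46, SE 0.132, adjusted p = 2.63e-11), from 16.9 ± 1.12 to 3.07 ± 0.759 CPM. The trefoil peptides TFF1 and TFF2, secreted by mucosal epithelia, were 5.22-fold and 3.57-fold lower. APOA4, an apolipoprotein of gut and liver, was 4.71-fold lower and APCS, the serum amyloid P component, 4.59-fold. Also lower were the dipeptidase DPEP1 (5.16-fold), the syntenin relative SDCBP2 (4.19-fold), the thyroid hormone deiodinase DIO1 (3.66-fold), S100A14 (3.63-fold) and the carbonic anhydrase CA4 (3.38-fold). The adjusted p of these 10 genes ran up to 1.94e-07. SLC30A1, the zinc exporter gene, was looked up after the metallothioneins were seen and was 2.37-fold higher (log2 fold change 1.24, SE 0.0585, adjusted p = 2.61e-12).

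**Figure D2:**
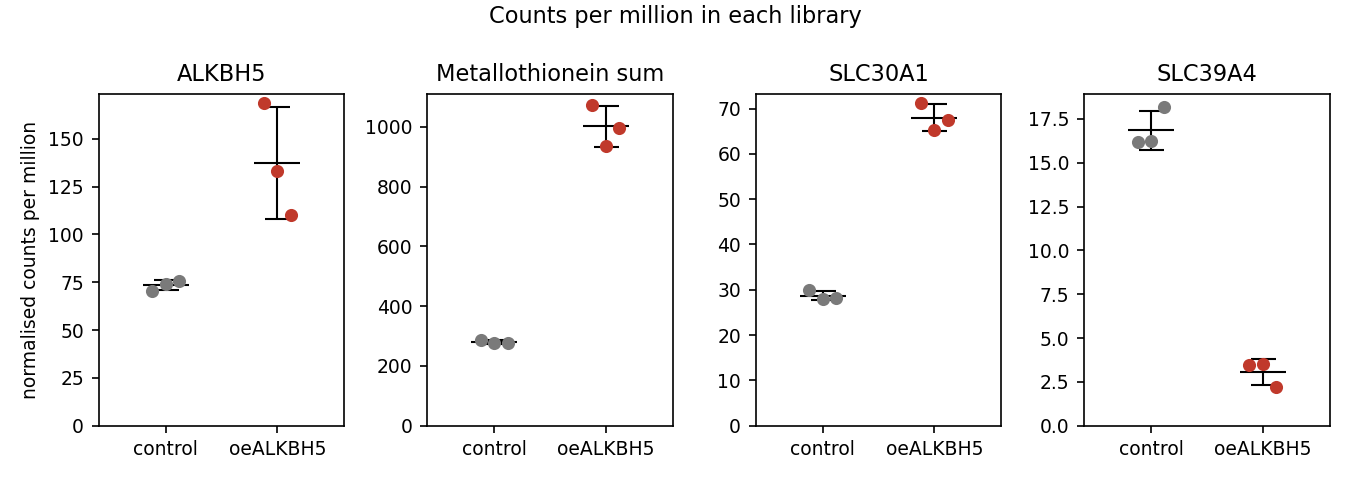
Normalised CPM in each library (points) with mean and SD (bars) for ALKBH5, the metallothionein sum, SLC30A1 and SLC39A4 in 3 control and 3 oeALKBH5 libraries. The groups do not overlap in any panel; the metallothionein sum lies at 937 CPM or more in oeALKBH5 and at 286 CPM or less in control.

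Of the 37 gene lists, 16 passed camera, 5 higher and 11 lower. With an estimated correlation 0 of them passed, and 5 had an unadjusted p under 0.05; by fry 25 lists passed, 8 higher and 17 lower. The lists that passed by fry and not by camera were, higher, the m6A erasers and readers, splicing and stellate lists and, lower, the p53, interferon, antigen presentation, heat shock, macrophage and cholangiocyte lists. Genes of lipid synthesis fell. In the cholesterol synthesis list, 22 of 24 genes fell and 0 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -0.73 (camera adjusted p = 4.14e-44; adjusted p = 0.116 with an estimated correlation). Examples were FDFT1, the squalene synthase, at -0.94 (SE 0.0451) and the mevalonate decarboxylase MVD at -1.13 (SE 0.0554). In fatty acid synthesis, 15 of 16 genes fell and 0 rose, also adjusted over the list alone, with a median of -0.45 (camera adjusted p = 3.57e-19; adjusted p = 0.116 with an estimated correlation). The stearoyl-CoA desaturase SCD went from 1325 ± 22.4 to 692 ± 35.6 CPM (-0.94), and the acetyl-CoA synthetase ACSS2 fell by 1.33 on the log2 scale.

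Genes of liver function fell as well. Of 33 liver secreted proteins 27 fell and 1 rose, also adjusted over the list alone, with a median of -0.44 (camera adjusted p = 2.67e-26; adjusted p = 0.116 with an estimated correlation). SERPINC1, which encodes antithrombin, was at -1.49 (SE 0.069) and APOA1, the main protein of high-density lipoprotein, at -1.05 (SE 0.0472); the copper carrier CP was the one that rose (0.60, SE 0.0511). Of 14 gluconeogenesis and amino acid catabolism genes 10 fell, among them AGXT (-1.08), while HPD (2.47-fold) and ARG1 (1.78-fold) rose, with the same counts adjusted over the list alone (median -0.44, camera adjusted p = 2.40e-04; adjusted p = 0.122 with an estimated correlation). Fatty acid oxidation had 11 of 20 lower, 13 adjusted over the list alone, led by the fatty acid binding protein FABP1 (-0.88), and 2 higher by either adjustment, the lipid droplet gene PLIN2 (0.52) and ANGPTL4 (1.01). Its median was -0.17 (camera adjusted p = 0.00613, and 0.449 with an estimated correlation). At -0.1679 it lay just inside the lower edge of random gene sets matched on transcript length and expression (-0.1681 to 0.05). Hepatocyte transcription factors went both ways: 5 rose and 7 fell of 18 (5 and 10 adjusted over the list alone), with PROX1 at 0.61 and ONECUT2 at -0.31 (camera adjusted p = 0.598); with library size alone it was 6 and 5. Bile acid and xenobiotic genes had 6 higher and 4 lower of 19 by either adjustment, such as ABCC3 (0.49) and GSTA1 (-0.87); the median was 0.07 and the mean 0.017, while camera pointed down (adjusted p = 0.929).

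Mesenchymal, matrix and hypoxia genes rose. In the mesenchymal and matrix list 16 of 23 rose and 2 fell (17 and 2 adjusted over the list alone, 18 and 0 with library size alone), with a median of 0.54 (camera adjusted p = 1.54e-11; adjusted p = 0.334 with an estimated correlation). VIM, the intermediate filament vimentin, went from 99.9 ± 4.55 to 179 ± 1.72 CPM (0.84, SE 0.0477), and the growth factor TGFB2 rose by 0.99 (SE 0.0695). SPARC fell (-0.21) and lost its call without oeALKBH5 replicate 2 (adjusted p = 0.0611) or control replicate 1 (0.0683). Of 18 epithelial and junction genes 10 fell, such as EPCAM (-0.98) and CLDN4 (-0.95), and CLDN1 (0.45) and DSP (0.34) rose; adjusted over the list alone 11 fell and 4 rose, and with library size alone 7 and 4 (median -0.19, camera adjusted p = 0.00752; adjusted p = 0.449 with an estimated correlation). In the hypoxia response 14 of 17 rose and 1, the prolyl hydroxylase subunit P4HA2 (-0.41), fell, also adjusted over the list alone. The median was 0.50 (camera adjusted p = 1.46e-07; adjusted p = 0.449 with an estimated correlation), with the histone demethylase KDM3A at 0.74 (SE 0.0581) and the oxygen sensor EGLN1 at 0.52 (SE 0.0606). Glycolysis had 6 higher and 3 lower of 19 by either adjustment. The pyruvate kinase genes moved apart, with PKM higher (0.57) and the liver form PKLR lower (-1.19); the list's camera adjusted p was 0.159, and 0.0465 without oeALKBH5 replicate 2. In the NF-kB and inflammatory list 12 of 22 rose, among them CSF1 (0.76), and NFKBIA, which encodes an inhibitor of NF-kB, fell (-0.32). Adjusted over the list alone 13 rose and 1 fell (median 0.35, camera adjusted p = 4.52e-05; adjusted p = 0.449 with an estimated correlation).

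**Figure D3:**
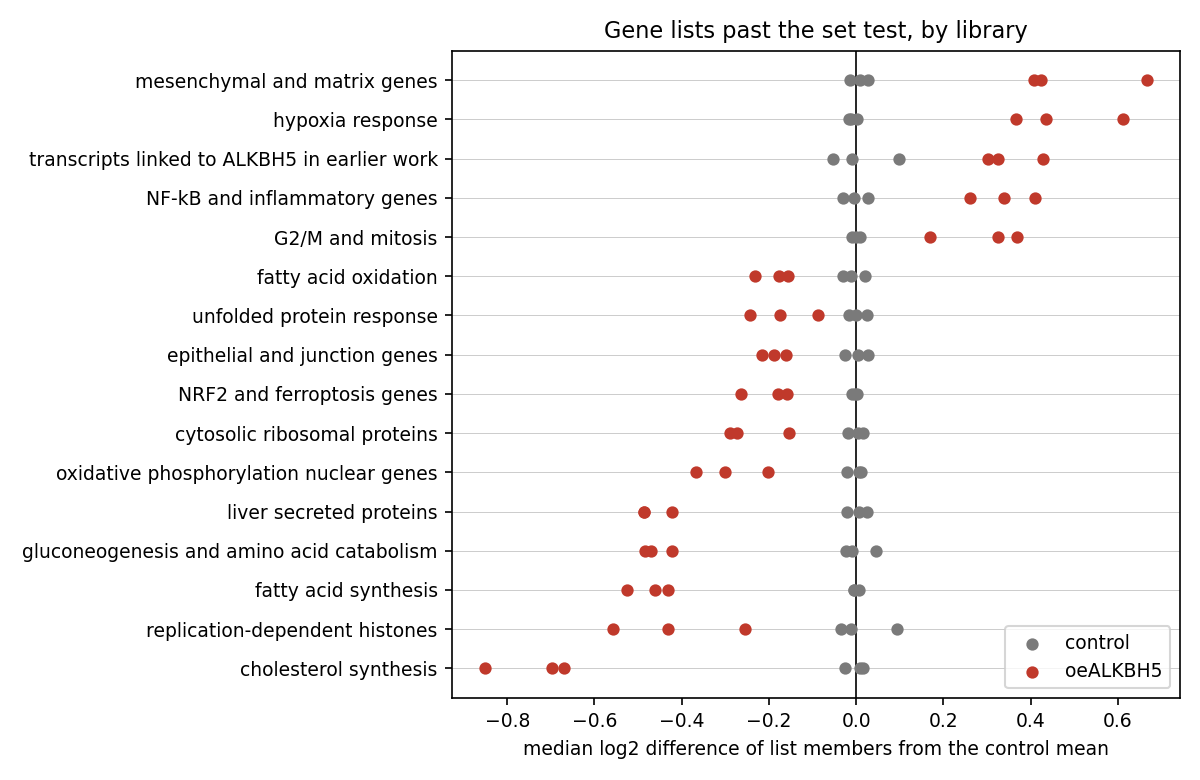
Median log2 difference from the control mean over the tested members of each list that passed camera, 1 point per library. The 3 oeALKBH5 libraries lie on one side of the 3 controls in every list shown, from -0.85 to -0.67 for cholesterol synthesis and from 0.41 to 0.67 for mesenchymal and matrix genes.

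Mitosis genes rose while ribosomal and respiratory mRNAs fell. Of 24 G2/M genes 19 rose and 0 fell, also adjusted over the list alone (median 0.29, camera adjusted p = 6.01e-09; adjusted p = 0.449 with an estimated correlation), led by the kinetochore genes CENPE (0.87, SE 0.0784) and CENPF (0.48, SE 0.0548). G1/S genes had 10 higher and 1 lower (MCM6, -0.21) of 24 by either adjustment, and 14 and 1 with library size alone; the camera adjusted p was 0.0653, and passed without oeALKBH5 replicate 1 (0.00874) or replicate 2 (0.0479), with upper quartile scaling (0.0471) and with library size alone (0.0146), in a range of 0.00874 to 0.733. Of 22 p53 targets 2 rose, TNFRSF10B (0.34) and BBC3 (0.39), and 7 fell, such as the cell cycle inhibitor CDKN1A (-0.86, SE 0.0636); adjusted over the list alone it was 3 and 7 (camera adjusted p = 0.244), and with library size alone 4 and 5. Of 53 cytosolic ribosomal protein genes 50 fell, 52 adjusted over the list alone, and 0 rose (median -0.25, camera adjusted p = 3.28e-12; adjusted p = 0.449 with an estimated correlation), with RPS2 at -0.27 and RPL15 at -0.19. With library size alone 39 of them fell. Of 29 nuclear oxidative phosphorylation genes 26 fell and 0 rose, also adjusted over the list alone (median -0.26, camera adjusted p = 3.48e-10; adjusted p = 0.449 with an estimated correlation), such as COX5A (-0.52) and SDHB (-0.50). Fold changes also followed transcript length across genes, which are not independent replicates (Spearman rho 0.223, 13975 genes). Random sets matched on length and expression had medians from -0.2461 to -0.137 for the ribosomal list. Its own median of -0.246 lay just inside the lower edge, with 287 of 10000 sets as low. For the respiratory list the sets ran from -0.22 to -0.04, and its median lay below, with 10 of 10000 sets as low. The replication-dependent histone list, like the ribosomal list, was set as a quality check and not as a pathway. Of 15 histone genes 4 fell (H1-2, H2AC6, H2AC13 and H2BC5), 0 rose and 11 did not pass, with the same counts adjusted over the list alone. The list's median was -0.54 (camera adjusted p = 0.0437; adjusted p = 0.449 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0709) and with the replicate block (adjusted p = 0.0643), in a range of 0.00993 to 0.449, and H2AC13 lost its call without control replicate 2 (adjusted p = 0.0687) and H1-2 with that block (adjusted p = 0.0703).

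Genes of the antioxidant and unfolded protein responses mostly fell. Of 24 NRF2 and ferroptosis genes 15 fell, such as the glutathione peroxidase GPX2 (-0.79) and the ferritin light chain FTL (-0.41), and AKR1C1 (0.37), AKR1C2 (0.18) and SLC40A1 (0.25) rose. Adjusted over the list alone 17 fell and 3 rose (median -0.20, camera adjusted p = 4.47e-04; adjusted p = 0.403 with an estimated correlation). Of 18 unfolded protein response genes 12 fell, among them SEC61B (-0.44) and MANF (-0.32), and CALR (0.13) rose, a call lost without control replicate 2 (adjusted p = 0.0976) or 3 (0.0733). With library size alone 5 fell and 2 rose; adjusted over the list alone 13 fell and 2 rose (median -0.18, camera adjusted p = 0.0224; adjusted p = 0.449 with an estimated correlation). The list lay inside its length-matched range (-0.18 to 0.03), and with library size alone, a setting chosen after seeing the data, its adjusted p was 0.0574, in a range of 0.00519 to 0.449. The remaining stress and immune lists did not pass camera, and several splits changed with scaling. ATF4 targets had 4 higher and 10 lower of 20 by either adjustment, with VLDLR at 0.73 and ASNS at -0.46 (adjusted p = 0.437). Heat shock genes had 0 higher and 5 lower of 15 by either adjustment, including HSP90AA1 (-0.33), and 2 and 3 with library size alone; their median was 0.0042, the mean -0.064 and camera pointed down (adjusted p = 0.437). Interferon-stimulated genes had 4 higher and 10 lower of 31 by either adjustment, with IRF9 at 0.39 and OAS1 at -0.73 (adjusted p = 0.437), but 6 and 5 with library size alone and 1 and 6 by DESeq2. Antigen presentation had 1 higher, TAPBP (0.26), and 9 lower of 14, such as PSMB10 (-0.53); it was 2 and 9 adjusted over the list alone (adjusted p = 0.159), and 2 and 4 with library size alone. Acute phase and complement genes had 5 higher and 5 lower of 17 by either adjustment, from HAMP, the iron hormone hepcidin, at -1.15 to C1S at 0.74 (adjusted p = 0.577). Autophagy and lysosome genes had 4 higher and 10 lower of 25, or 4 and 11 adjusted over the list alone, with CTSB at 0.30 and CTSL at -0.35 (adjusted p = 0.437), but 7 and 6 with library size alone. Immediate early genes had 4 higher and 4 lower of 20 by either adjustment, with IER3 at 0.70 and KLF4 at -0.82 (adjusted p = 0.867).

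Some genes of the m6A machinery other than ALKBH5 passed, beside 42.8% of all tested genes. Most of the m6A calls were lost with 1 library or another left out. The log2 fold changes of METTL3 (-0.195 to -0.090), ZC3H13 (0.149 to 0.242) and IGF2BP1 (0.133 to 0.149) kept their sign in those fits. A lost call there does not show that 1 library carried the change. Among 11 writer subunits RBM15 rose (0.58, SE 0.107), as did WTAP (0.12) and ZC3H13 (0.19), and the catalytic subunit METTL3 fell (-0.14); adjusted over the list alone 2 rose and 0 fell (camera adjusted p = 0.841). ZC3H13 lost its call without control replicate 3 (adjusted p = 0.0889). METTL3 lost it without any one library except oeALKBH5 replicate 3 (adjusted p = 0.0638 to 0.167), and also by DESeq2 (0.0854), with upper quartile scaling (0.0839), with library size alone (0.37) and with a mean count of at least 50 (0.0542), in a range of 0.00527 to 0.37. WTAP lost it without any one library except oeALKBH5 replicate 1 (0.0615 to 0.145). Of 15 other erasers and readers 5 rose and 0 fell by either adjustment (camera adjusted p = 0.255; fry adjusted p = 0.00835), and 9 rose with library size alone. IGF2BP2 (0.25, SE 0.0519) passed with each library left out. IGF2BP1 (0.14) lost its call without control replicate 2 (adjusted p = 0.0603), IGF2BP3 (0.16) without oeALKBH5 replicate 2 or any control replicate (0.0598 to 0.124), HNRNPA2B1 (0.18) without oeALKBH5 replicate 2 (0.0541) or control replicate 1 (0.0925), and PRRC2A (0.13) without oeALKBH5 replicate 2 (0.0731) or control replicates 2 and 3 (0.111 and 0.174). Other AlkB family members had 1 higher and 2 lower of 7 by either adjustment, with ALKBH7 at -0.27 (camera adjusted p = 0.718). ALKBH2 (0.26) lost its call without any one library except oeALKBH5 replicate 1 (adjusted p = 0.0764 to 0.126), and ALKBH6 (-0.20) without oeALKBH5 replicates 2 and 3 or control replicates 1 and 3 (0.06 to 0.223). In the list of transcripts linked to ALKBH5 in earlier work, 4 of 8 rose, TACC3 (0.41, SE 0.0461), PER1 (0.38), MAP3K8 (0.42) and FOXM1 (0.22), and 0 fell, also adjusted over the list alone (median 0.39, camera adjusted p = 0.0224; adjusted p = 0.334 with an estimated correlation). Splicing and RNA export genes had 12 higher and 7 lower of 28 by either adjustment, with HNRNPH1 at 0.46 and HNRNPA1 at -0.24 (camera adjusted p = 0.231; fry adjusted p = 0.044), but 13 and 2 with library size alone. Wnt and liver progenitor genes had 8 higher and 5 lower of 20, or 8 and 6 adjusted over the list alone, with LGR5 at 0.75 and the oncofetal proteoglycan GPC3 at -0.84 (camera adjusted p = 0.591).

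Markers of other cell types moved in both directions. Cholangiocyte markers had 3 higher and 5 lower of 11 by either adjustment, including ANXA4 (-0.31); the camera adjusted p was 0.0513, and passed without oeALKBH5 replicate 1 (0.0143), oeALKBH5 replicate 2 (0.0479) or control replicate 2 (0.0335), with the replicate block (0.0395), upper quartile scaling (0.0456) or library size alone (0.0443), and by fry (0.0102), in a range of 0.0102 to 0.449. Stellate and fibroblast markers had COL1A1 (1.07) and COL1A2 (0.92) higher and LUM (-0.55) lower of 8 by either adjustment (camera adjusted p = 0.512; fry adjusted p = 0.0102, higher), LUM without a call when oeALKBH5 replicate 2 (adjusted p = 0.0507) or control replicate 1 (0.0732) was left out. Of 6 macrophage and leukocyte markers 1, MARCO (-0.84), fell by either adjustment (camera adjusted p = 0.676; fry adjusted p = 0.015, lower), and CD68 stood at 138 ± 14 and 138 ± 1.93 CPM. PECAM1 (-0.70) was the 1 endothelial marker tested. Among 15 housekeeping references 2 rose, HPRT1 (0.52) and POLR2A (0.30), and 5 fell by either adjustment (camera adjusted p = 0.606; 3 and 2 with library size alone), while ACTB was at 4281 ± 88.7 and 4249 ± 72.1 CPM.

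On the authors' FPKM values, limma called 5512 of 12016 genes. Of 12015 genes tested both ways, edgeR called 5664 and limma 5511. Both called 4548, and all 4548 had the same sign. FPKM values and counts describe the same transcripts in the same libraries, so this is not an independent check.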

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

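The list test under upper quartile scaling and library size alone was chosen after seeing the data; the other alternatives were planned. The number of changed genes (6062) ran from 4248 at an adjusted p under 0.01 to 6468 with the replicate number as a block, and from 4878 to 6353 with 1 library left out. Same-numbered libraries did not deviate together over all genes (correlations -0.0193, 0.0162 and -0.0123), so no broad shift by number was seen. No label says whether the numbers mark a shared day or transfection, and these correlations cannot exclude it. The block changed the call of ALKBH5 (log2 fold change 0.89), H1-2 and the histone list. It also gave LYZ and the cholangiocyte list a call, and changed no other call among named genes and lists.

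A mean count of at least 50 kept 147 genes past an absolute log2 fold change of 1, 76 higher and 71 lower, since it tests fewer low genes. Library size alone gave 2047 lower genes; it leaves the lower share of the most abundant genes in oeALKBH5 uncorrected. ALKBH5 ran from 0.73 to 1.04 on the log2 scale with 1 library left out, always higher. Its adjusted p rose past the threshold without control replicate 2 (log2 fold change 0.91) and 3 (0.92), and also with the block, which keeps all libraries. The cause was not tested. With an estimated correlation 0 lists passed camera (0 higher and 0 lower), and fry passed 25 lists, 8 higher and 17 lower, since it compares a list with no other genes.

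ACTB (0.011) turned to -0.0037 without oeALKBH5 replicate 1 and reached 0.027 with another library left out. CD68 (-0.0012) turned to 0.0013 with DESeq2 size factors and with DESeq2, 0.018 with upper quartile scaling, 0.078 with library size alone, 0.0021 with the CPM filter and 0.0084 with the mean count filter; it ran from -0.086 to 0.050 with 1 library left out. Neither gene passed in any of these settings, and the cause was not tested. Of 2125 settings of 133 named genes, 2058 kept direction and side of the threshold, 48 lost a call, 8 gained one and 11 reversed, all 11 in ACTB and CD68. Calls lost with 1 library left out include genes of a few CPM, such as PNCK and FSBP, and small changes of more abundant genes, such as METTL3. The log2 fold changes of PNCK, FSBP and METTL3 kept their sign in those fits.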

Other observations

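The lists and tests on metallothioneins, zinc transporters, stress genes, intestinal genes, actin genes, YAP targets and interferon-stimulated genes were chosen only after the result was seen; those on transcript length over both lists, exon length and splits of the samples were written before. Genes of the intestinal epithelium, many of which Huh-7 expresses, fell together. Of 27 tested, 26 fell and 0 rose, with a median log2 fold change of -1.09 (camera adjusted p = 6.39e-53 over 10 such list tests; adjusted p = 0.0085 with an estimated correlation). Leaving out genes already seen among the largest changes, 13 of 14 fell (median -0.56, camera adjusted p = 3.87e-12, and 0.0288 with an estimated correlation). This list and the others chosen after the result was seen were prompted by these same data. Their p-values, also without the genes seen first, describe the pattern and are not independent support for it. The retinol binding protein RBP2 was 3.05-fold lower (SE 0.0539 on the log2 scale), the alkaline phosphatase ALPI 2.38-fold, and the anion exchanger SLC26A3 2.82-fold. CDX2, the transcription factor of intestinal identity, fell by 0.40 on the log2 scale (SE 0.0481).

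Actin cytoskeleton genes, many of them targets of the transcription factor SRF, leaned the other way. Of 19 tested, 14 rose and 1, TAGLN2 (-0.30), fell (median 0.27, camera adjusted p = 5.78e-10; adjusted p = 0.209 with an estimated correlation). Without the genes seen first, 11 of 16 rose (adjusted p = 2.60e-05; adjusted p = 0.246 with an estimated correlation). TAGLN was 2.85-fold higher, CSRP1 2.57-fold and the tropomyosin TPM2 1.91-fold, while SRF itself stood at 0.079 (adjusted p = 0.276). Of 8 metallothionein genes tested 7 rose (median 1.44, camera adjusted p = 4.47e-47; adjusted p = 0.00575 with an estimated correlation). Without those seen first 2 of 3 rose, and the estimated correlation lost the call (adjusted p = 0.00274; adjusted p = 0.091 with an estimated correlation).

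The rise of metallothionein mRNAs was weighed against 3 explanations. Reads moved only between near-identical copies would leave the family sum in place, yet the lowest oeALKBH5 library held 3.27 times the highest control. The members had already been seen, with 7 of 8 higher and 0 lower, so the sum was bound to rise. It shows a rise of the family as a whole. The size of a single member's rise, such as MT1X at 20.6-fold, stays uncertain. For general oxidative or protein-damage stress, HMOX1, a standard marker, was at -0.20 (SE 0.0489), and 0 of 12 stress genes were higher and 5 lower. That argues against stronger stress of this kind in oeALKBH5 cells than in controls at 60 h. It cannot exclude an earlier stress, or one that the controls shared. Raised free zinc remains a candidate explanation: the exporter SLC30A1 rose by 1.24 and the importer SLC39A10 changed by -0.91 (SE 0.0691), the opposite directions that the metal-responsive factor MTF1 gives. Other metals that act through MTF1, a difference in medium, and ALKBH5 itself stay open, since no label separates them from the groups.

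Lower liver and sterol genes with higher matrix genes could come from the plasmid or the handling rather than from ALKBH5. Of interferon-stimulated genes 12.9% were higher (4 of 31, and 6 of 31 with library size alone). Among all tested genes 2948 of 14168 were higher in the main test, so 4 of 31 is no excess. That argues against a stronger interferon response in oeALKBH5 cells than in controls at 60 h. It cannot exclude an earlier response to plasmid DNA, or one that the controls shared if they received a plasmid. Lower culture density cannot be told apart from the groups: YAP and TEAD targets, which cell contact keeps low, had a median of 0.25 with 11 of 21 higher and 1 lower (camera adjusted p = 3.06e-05; adjusted p = 0.209 with an estimated correlation), but ALKBH5 might raise them too. The number of cells per culture and the treatment of the controls are not given in the labels, so electroporation itself stays untested.

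Lower ribosomal and respiratory mRNAs may partly follow transcript length. The median of both lists together (-0.25) lay 0.079 below that of sets matched on length and expression (difference -0.0787; matched range -0.22 to -0.12). It fell below that range, but by less than the margin set beforehand for excluding length, so length bias cannot be told apart from a change of these genes. Pairs of libraries within a group also differed by length, with rho up to 0.263. A loss of m6A from transcripts with long exons, where m6A concentrates, would give a positive link with longest exon if the loss raised their mRNA levels. That direction was assumed, and m6A itself was not measured here. The raw rank correlation was 0.146 (up to 0.186 between libraries of a group). With length, GC content and expression removed it was -0.049, smaller in size than the largest between libraries of a group (0.0724). These values give that explanation no support. The longest exon is part of transcript length, so removing length may also have removed some of the link.

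Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 6062 genes and the highest of the others 0, so 1 of the 10 splits gave as many. Each other split mixes libraries of both groups, so a strong group difference of any origin would give few calls in it.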
